A study of Oryza sativa with 12 samples.

How the data were processed

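Poly(A) RNA was sequenced from callus of 3 wild-type and 3 hk3,4,5,6 mutant lines, each treated for 1 h with 5 µM BA or with vehicle, giving 12 strand-specific libraries. Per the labels' protocols, mRNA was enriched with oligo(dT) beads, the second cDNA strand carried dUTP, and sequencing used a DNBSEQ-T7 instrument. The deposited files, 1 per library, hold for each of 42789 transcripts an estimated count, per the file headers, in which reads shared between transcripts were divided by the quantifier. They also hold TPM, a length-scaled relative abundance, computed by the authors from effective transcript lengths, per the file headers. Per the submitters' processing notes, kallisto 0.46.1 and the genome build IRGSP-1.0 were used, while the transcript set, index and options are not given in the sources used here. Between 35.6% and 36.8% of the estimated counts were not whole numbers.

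Estimated counts were summed over the transcripts of each gene, giving 35813 genes (5475 with more than 1 transcript), and rounded to whole numbers. Totals lay between 22393326 and 22656063 per library (largest over smallest 1.01), between 29049 and 29381 genes were above 0, and between 23847 and 24423 had 10 counts or more. The 10 most abundant genes took 3.99% to 5.34% of the counts, chloroplast transcripts at most 0.000622% and mitochondrial transcripts at most 0.00168%. Another 118 entries carried names other than gene IDs. The value for a gene that shares reads with a near-identical copy is uncertain, as for Os11g0143300 and Os12g0139400, for which the sum is also given. Counting intervals (95%, conditional exact binomial) cover counting error only. Floors of 3 counts over a group cover only the counting error of the group at 0, and not that of the higher group.

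Genes were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr with the 4 groups (minimum count 10, minimum total 15), which kept 25241 genes, TMM scaling (factors 0.951 to 1.08), 1 mean per group, and the quasi-likelihood fit and F test without robust estimation (8 residual degrees of freedom, biological coefficient of variation 0.195). Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The comparisons were BA against vehicle in each genotype, the difference of these responses (interaction), and mutant against wild type under each treatment. Log2 CPM used a prior count of 2. Correlations between libraries of a group, across genes, were 0.965 to 0.984. The overlap of the BA response with the genotype difference was set against n1 × n2 / N and against simulated unchanged groups, because the wild-type vehicle libraries serve in both. With 3 vehicle libraries the controls could not be split into parts of at least 2.

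The design, the alternatives, the rule for named genes and 8 gene lists were fixed before the data were examined. These 8 hold disrupted cytokinin receptors, type-A and type-B response regulators, histidine phosphotransfer proteins, cytokinin oxidases, cytokinin synthesis, KNOX and WOX meristem regulators, and fermentation enzymes. A further 14 lists were given gene IDs afterwards, 11 of them for themes named beforehand by description, which could not be used because the files hold no descriptions. They hold Aux/IAA repressors, GH3 enzymes, auxin efflux carriers, JAZ repressors, WRKY factors, pathogenesis-related proteins, heat shock proteins, cyclins, nitrate transport and assimilation, clock genes, stress factors, and markers of green cells (light-harvesting and photosystem genes), endosperm (seed storage proteins) and embryo (late embryogenesis abundant proteins and oleosins). Another 2 lists took chloroplast and mitochondrial transcripts from names in the files. List members were entered by locus ID from general knowledge of the rice genome. All 229 IDs occur in the files. The reference annotation, of the assembly ASM3414082v1, matched 1 of the files' IDs and so could not name them. It lists the symbol entered for 171 of the 229, on the chromosome the ID implies for 165 and on another for 6, so single list memberships are uncertain and no symbols are printed.

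Lists of at least 3 tested members were tested with limma 3.58.1's camera (preset correlation 0.01) and adjusted over the lists of the same origin within a comparison, and again with the correlation estimated per list. The genes that rose in wild-type callus were tested as a set in the mutant with fry, a directional set test that does not compare the set with other genes. Fry was also run on the lists, and its calls are given with the alternatives. Neighbouring pairs of called genes were set against 10000 random draws of tested genes. For lists fixed beforehand, members were also adjusted over the list alone. Named genes were, for each comparison, the 4 receptors and each tested type-A regulator, up to 4 members of each list with the smallest adjusted p below the threshold, and the 10 rising and 10 falling genes of largest log2 change with a mean log2 CPM of at least 1 and the same sign in every line (BA comparisons) or no overlap between groups (genotype comparisons). Since files and reference pair no names with the IDs, at most 2 rising and 2 falling genes outside the lists are printed per comparison.

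BA and vehicle libraries of a line come from the same callus line per the labels, so they are paired. Their deviations from the group means correlated across genes at 0.553, 0.456 and 0.286 for mutant lines 13, 54a and 54b, and at 0.0772, −0.00672 and −0.279 for wild-type lines A1, B1 and B4. The fit with the line as a block left 4 residual degrees of freedom and is given beside a result where it changed a call.

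The fit was tested on counts simulated from the wild-type vehicle means and the library sizes, with independent draws per library and so no line effect. In these, 24457 genes were tested and 200 changed, 50 per fold size, all with a mean of at least 1 CPM. Recovery of genes below that level, or with line effects, was not tested. For the BA response of wild-type callus the fit recovered 94% and 100% of genes changed by log2 −2 and 2, and 56% and 60% of those changed by −1 and 1, with 3 of 158 calls among unchanged genes. For the interaction it recovered 90% and 72% at −2 and 2, and 26% and 22% at −1 and 1, with 5 of 110 calls among unchanged genes. For the genotype difference under BA it recovered 100% and 90% at −2 and 2, and 62% and 60% at −1 and 1, with 10 of 166 among unchanged genes. With no change simulated, the BA response of the mutant and the genotype difference under vehicle gave 0 calls.

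The alternatives were DESeq2 size factors and upper-quartile scaling, a filter of 1 CPM in 3 libraries and no filter, counts scaled from TPM by length, limma-trend on log2(TPM + 1), the DESeq2 1.42.0 Wald test, limma-voom, the line as a fixed block and as a random effect (correlation 0.0966), only the groups compared, stricter thresholds, and each library or line left out. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates were not used, because no annotation of the build was at hand. Printed values are rounded.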

Results

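RNA was sequenced from rice (Oryza sativa, cultivar Kitaake) callus, an unorganised tissue grown here from seeds. Wild-type callus was compared with callus of an hk3,4,5,6 quadruple mutant, in which 4 histidine kinase genes that encode cytokinin receptors are disrupted. Each genotype had 3 callus lines (A1, B1 and B4 for wild type, and 13, 54a and 54b for the mutant). The labels do not say whether 54a and 54b derive from the same plant. They were treated as separate lines, and if they share an origin the mutant has fewer than 3 independent origins, which would weaken every p value that involves it. The sample titles give no origin for the wild-type lines either. If B1 and B4 share one, the same limit holds for wild type. Each line gave 1 library after 1 h in nutrient solution with 5 µM 6-benzylaminopurine (BA), a synthetic cytokinin, and 1 library after 1 h with vehicle. The 12 libraries thus formed 4 groups of 3. Estimated counts summed to between 22393326 and 22656063 per library, and 25241 of 35813 genes were tested. Expression levels are library-scaled counts (CPM) with the SD over n = 3 libraries, and log2 changes carry the standard error of the fit to all 12 libraries. Genes are named by locus ID, because the files do not pair IDs with symbols.

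The disrupted receptor genes were examined first, in every library. Os03g0717700 lay between 7.11 and 10.02 CPM in the 6 mutant libraries and between 19.8 and 40.5 CPM in the 6 wild-type libraries. Os02g0738400 lay between 10.6 and 17.94 CPM in mutant libraries and between 22.9 and 32.9 CPM in wild-type libraries. Under vehicle, Os03g0717700 was lower in the mutant by log2 −1.46 ± 0.16 (edgeR adjusted p = 0.00053) and Os02g0738400 by −0.97 ± 0.17 (edgeR adjusted p = 0.0075). Os01g0923700 was lower by −0.80 ± 0.15, from 44.0 ± 6.54 to 25.4 ± 4.04 CPM (edgeR adjusted p = 0.01), and Os10g0362300 did not pass, at 25.8 ± 4.76 and 18.03 ± 5.53 CPM (edgeR adjusted p = 0.2). Thus 3 of the 4 genes passed over all genes tested under vehicle, and 4 when adjusted over the list alone. Under BA 2 passed, Os03g0717700 and Os02g0738400, and 3 did when adjusted over the list alone. As a list, the receptors were lower in the mutant under vehicle (camera adjusted p = 6e-08, and adjusted p = 0.038 with an estimated correlation) and under BA (camera adjusted p = 9.4e-07, but adjusted p = 0.06 with an estimated correlation). Transcripts of all 4 genes remained at 8.41 CPM or more in the mutant group means, and the counts do not show whether those transcripts are altered. The edgeR call of Os01g0923700 under vehicle ended without the wild-type vehicle library of line B1 (adjusted p = 0.0546), without line A1 (adjusted p = 0.0591) and without line B1 (adjusted p = 0.0515).

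**Figure D1:**
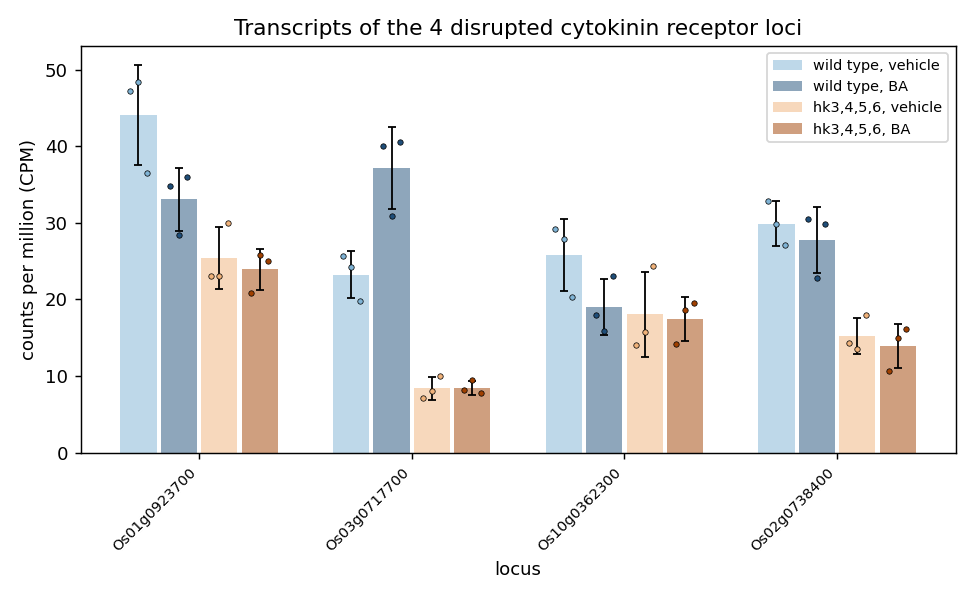
CPM of the 4 disrupted receptor genes, by locus ID, in each of the 12 libraries, with the mean and SD of each group of 3. Os03g0717700 and Os02g0738400 lie lower in all 6 mutant libraries than in any wild-type library.

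The BA response of wild-type callus asked which genes a brief cytokinin treatment moved. Type-A response regulators, which are induced by cytokinin and dampen its signalling, rose together. Of 10 tested members 8 rose, 0 fell and 2 did not pass. Os04g0673300 rose 18.4-fold, from 22.9 ± 7.43 to 421 ± 118 CPM (log2 4.20 ± 0.29, edgeR adjusted p = 7.4e-06). Os01g0952500 rose 12.2-fold, from 14.3 ± 1.60 to 174 ± 31.3 CPM, and Os04g0524300 rose by log2 4.50 ± 0.31, from 5.69 ± 2.38 to 130 ± 31.2 CPM. The near-identical pair Os11g0143300 and Os12g0139400, whose reads may be divided between them with error, summed to 1.97 ± 0.80 CPM under vehicle and 80.0 ± 16.0 CPM under BA. Os07g0449700 had 2 counts over the vehicle group and 67 over the BA group, a ratio of 34.3 (95% counting interval 9.12 to 289). Adjusted over the list alone, 9 members rose.

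Cytokinin oxidases, which degrade cytokinin, also rose in wild-type callus, with 5 of 7 tested members past the test, 0 fallen and 2 not passed. Os01g0775400 rose 11.9-fold, from 16.6 ± 4.51 to 197 ± 43.4 CPM (log2 3.58 ± 0.29, edgeR adjusted p = 2.8e-05). Os01g0197700 rose 11.5-fold, to 63.0 ± 11.6 CPM, and Os08g0460600 rose 3.79-fold, from 70.1 ± 2.21 to 266 ± 26.0 CPM. Adjusted over the list alone, 7 rose. Camera called both lists higher, at adjusted p = 6.5e-127 for the type-A regulators and adjusted p = 1.5e-62 for the oxidases (adjusted p = 2.5e-06 for each with an estimated correlation).

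**Figure D2:**
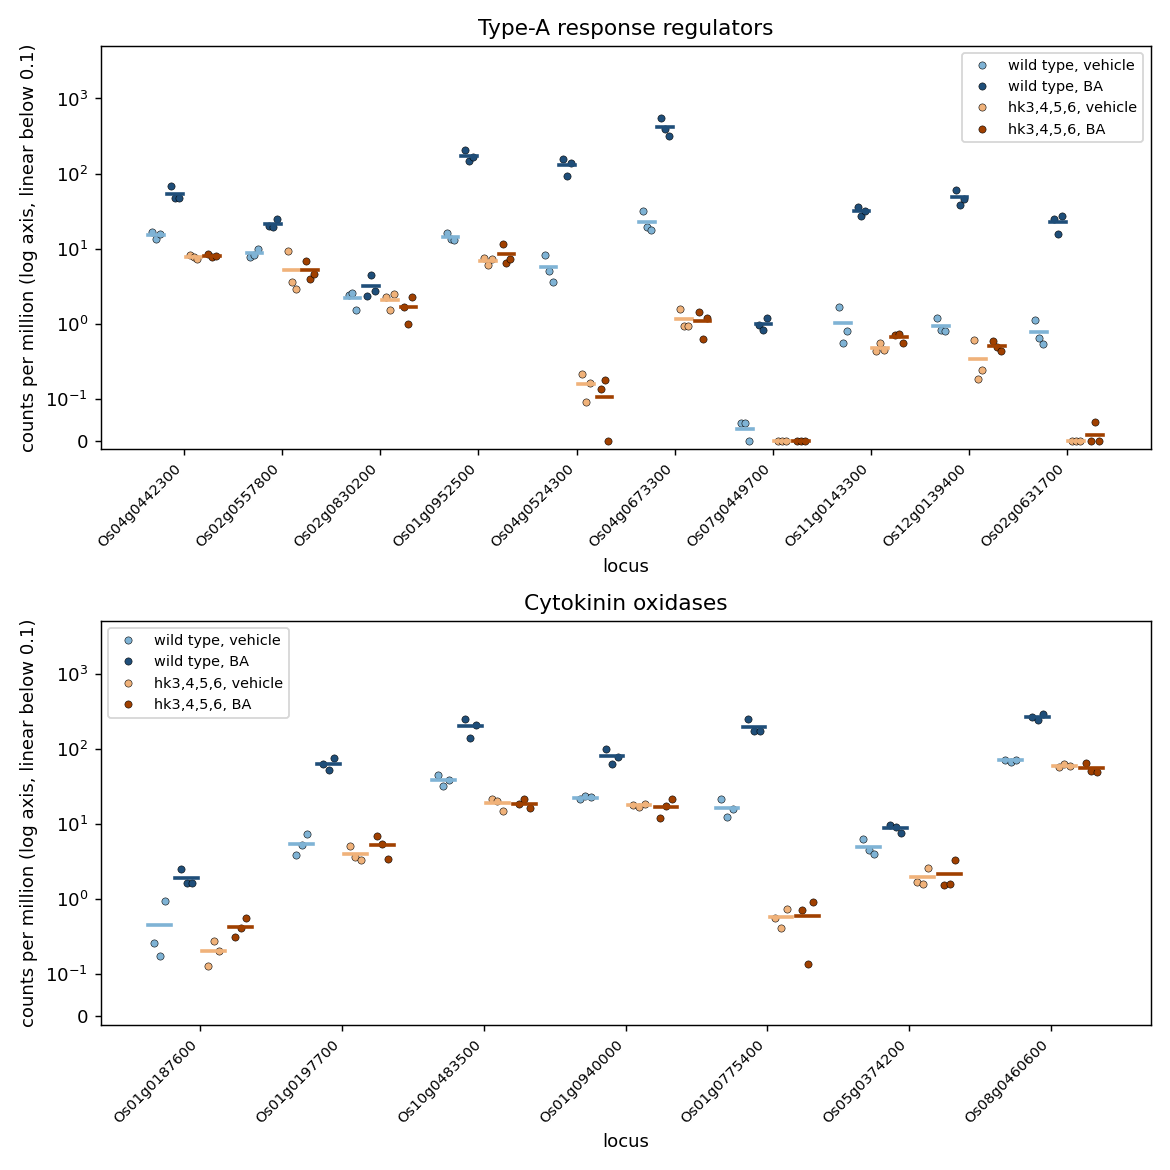
CPM, on an axis that is logarithmic above 0.1 and linear below, of tested type-A response regulators and cytokinin oxidases, each point a library and each bar a group mean of 3. In wild-type callus Os04g0673300 moved from 22.9 to 421 CPM with BA, and in mutant callus it stood at 1.16 and 1.1 CPM.

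Beyond these lists, 2 of 13 cytokinin synthesis genes rose with BA in wild-type callus, Os01g0588900 (log2 0.90 ± 0.16) and Os08g0429800 (1.74 ± 0.25), while 3 were higher and 1 lower when adjusted over the list alone. That list did not pass camera (adjusted p = 0.068), but did with the callus line as a block (adjusted p = 0.021), and without the block gave adjusted p = 0.15 with an estimated correlation. No member passed among the 5 type-B response regulators, the transcription factors of the pathway (2 higher adjusted over the list alone), the 2 histidine phosphotransfer proteins, the 7 KNOX and WOX meristem regulators, the 4 fermentation enzymes or the 4 receptors (1 higher and 1 lower adjusted over the list alone). Among lists given IDs later, 1 of 10 GH3 auxin-conjugating enzymes rose (Os01g0785400, log2 2.33 ± 0.35, edgeR adjusted p = 0.0042), as did 1 of 11 JAZ jasmonate repressors (Os09g0401300, 0.67 ± 0.09) and 1 of 9 circadian clock genes (Os01g0971800, 1.41 ± 0.18). Of 6 auxin efflux carriers 2 rose and 1 fell, Os11g0137000 (−0.74), whose edgeR call ended with the line as a block (adjusted p = 0.055). The higher ones, Os06g0232300 and Os02g0743400, lost their edgeR calls in 8 and 5 of 29 alternatives (up to adjusted p = 0.211 and adjusted p = 0.159). Of 29 Aux/IAA auxin-response repressors 1 rose and 1 fell. Further, 1 of 7 nitrate genes rose and 1 of 8 light-harvesting genes rose. With the block, edgeR ended the calls of the risen Aux/IAA gene Os06g0597000 (adjusted p = 0.067) and the risen light-harvesting gene Os04g0457000 (adjusted p = 0.066). These edgeR calls also ended without single wild-type libraries, either library of A1 or B1 for Os06g0597000 (up to adjusted p = 0.131), of B1 or B4 for Os11g0137000 (up to adjusted p = 0.16) and of A1 or B4 for Os04g0457000 (up to adjusted p = 0.109). The risen nitrate gene Os08g0468100 lost its edgeR call in 19 of 29 alternatives, among them the omission of any wild-type library but the vehicle library of B4, of any mutant library but the vehicle library of 54b, and of any line (up to adjusted p = 0.374 without line B1). The fallen Aux/IAA gene Os01g0286900 lost its edgeR call in 13, among them the omission of any wild-type library (up to adjusted p = 0.182 for a library and adjusted p = 0.33 without line A1). No member passed among 15 WRKY factors, 12 cyclins, 11 heat shock proteins, 7 embryo genes (late embryogenesis abundant proteins and oleosins), 6 mitochondrial and 4 chloroplast transcripts, 5 stress factors, 3 pathogenesis-related proteins and 2 seed storage proteins. Camera passed 6 of these later lists, GH3 (adjusted p = 0.0031), JAZ (adjusted p = 0.0041), WRKY (adjusted p = 0.041), efflux carriers (adjusted p = 0.042), light-harvesting (adjusted p = 0.042, and adjusted p = 0.054 with the block) and nitrate genes (adjusted p = 0.044, with median log2 0.60 and mean −0.53). With an estimated correlation these 6 gave adjusted p = 0.45 for GH3 and efflux carriers, adjusted p = 0.49 for JAZ, WRKY and nitrate genes and adjusted p = 0.53 for light-harvesting genes. Cyclins passed with the block alone (adjusted p = 0.064 without it and adjusted p = 0.046 with it), and without the block gave adjusted p = 0.45 with an estimated correlation.

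In all, 350 genes passed edgeR's test in wild-type callus, 333 higher and 17 lower with BA, and 240 of the higher and 4 of the lower differed at least 2-fold. Outside the lists, Os03g0705800 rose from 1.98 ± 0.325 to 32.8 ± 9.17 CPM (log2 4.05 ± 0.32) and Os06g0220500 from 3.72 ± 0.778 to 55.9 ± 7.59 CPM (3.91 ± 0.42). Os03g0145900 fell by 1.00 ± 0.14 on the log2 scale, from 12 ± 1.7 to 6.02 ± 0.0883 CPM, and Os10g0560000 fell from 13.3 ± 4.36 to 5.34 ± 0.741 CPM. The 350 fell to 215 without the BA library of A1, to 171 and 158 without the vehicle libraries of A1 and B1, and to 93 and 118 without lines A1 and B1. Omissions of a library or line also ended edgeR calls of genes named here. These were Os07g0449700 (vehicle libraries of A1 and B1 and lines A1, B1 and B4, up to adjusted p = 0.17), Os01g0588900 (BA libraries of A1 and B1, each wild-type vehicle library and lines A1 and B1, up to adjusted p = 0.197), Os10g0560000 (BA libraries of A1 and B4, the vehicle library of A1 and lines A1 and B4, up to adjusted p = 0.193), and, without line A1 or B1, Os08g0429800, Os01g0785400 and Os03g0145900 (up to adjusted p = 0.102 for Os01g0785400). Os09g0401300 lost its edgeR call without line A1 (adjusted p = 0.0504). The type-A gene Os02g0557800, at 8.71 ± 1.11 and 21.5 ± 2.81 CPM, passed edgeR only with the block (adjusted p = 0.0099), without the mutant vehicle library of line 13 (adjusted p = 0.00831), without line 13 (adjusted p = 0.00178), in a fit of wild-type libraries alone or with other tools.

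In mutant callus no BA change passed. Os04g0673300 stood at 1.16 ± 0.384 CPM under vehicle and 1.1 ± 0.42 CPM under BA, Os01g0952500 at 6.92 ± 0.774 and 8.45 ± 2.72 CPM, and Os08g0460600 at 60.1 ± 2.93 and 55.0 ± 9.41 CPM. The pair Os11g0143300 and Os12g0139400 summed to 0.828 ± 0.185 and 1.18 ± 0.161 CPM. Of 10 type-A regulators and 7 cytokinin oxidases 0 passed, over all genes or adjusted over the list alone, and neither list passed camera (adjusted p = 0.86 for each). The edgeR count was 0 of 25241 genes, with 268 at an unadjusted p under 0.05 (376 with the line as a block). Chance alone would give 1262, so this test was conservative in mutant callus and may have missed small changes. It took the spread from both genotypes and did not use the pairing. An unpaired edgeR fit of the mutant libraries alone also called 0 genes, with 272 at an unadjusted p under 0.05. A paired fit of the mutant lines alone was not run. DESeq2 called 2 genes and limma-voom 0. The median standard error of the log2 changes was 0.195, and 90% of genes had one below 0.471. Camera placed 3 of the later lists higher with BA in the mutant, the 7 embryo genes (median log2 0.61, adjusted p = 1e-06, but adjusted p = 0.32 with an estimated correlation), and the JAZ and WRKY lists (adjusted p = 0.028 each, but adjusted p = 0.67 each with an estimated correlation), with no member past edgeR's test.

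The difference of the BA responses between genotypes was tested itself, as an interaction. Type-A regulators and cytokinin oxidases responded less in the mutant, with 5 of 10 and 5 of 7 members past the test and 0 in the other direction. For Os01g0952500 the response was smaller by log2 −3.32 ± 0.29 (edgeR adjusted p = 0.00055), for Os12g0139400 by −5.12 ± 0.56 (edgeR adjusted p = 0.0019) and for Os04g0673300 by −4.27 ± 0.50 (edgeR adjusted p = 0.0026). Os12g0139400 and its near-identical copy Os11g0143300 both passed. Their reads may be divided with error, which the standard errors do not cover, so they are not separate measurements. For the oxidases Os08g0460600 and Os01g0197700 it was smaller by −2.05 ± 0.17 (edgeR adjusted p = 0.00055) and −3.15 ± 0.39 (edgeR adjusted p = 0.0038). Os04g0524300, near 0 in the mutant, did not pass, at −5.09 ± 1.11 (edgeR adjusted p = 0.14). Adjusted over the list alone, the difference was below 0 for 7 type-A regulators, 5 oxidases, 2 synthesis genes, 1 type-B regulator and 1 receptor. It was above 0 for 1 synthesis gene. By the same adjustment 1 synthesis gene fell with BA in wild-type callus and 0 passed in the mutant. A difference above 0 thus need not be a larger response in the mutant. Outside the lists, Os03g0705800 (−3.84 ± 0.60) and Os01g0153800 (−3.75 ± 0.34) responded less.

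In all 54 genes passed the interaction test, each with the smaller or opposite response in the mutant, and all 54 were among the 333 genes that rose in wild-type callus. The interaction uses the same wild-type libraries that chose the 333, so this containment is not independent of that choice. DESeq2 called 171, with 12 in the other direction. At an unadjusted edgeR p under 0.05 lay 1019 genes, where chance alone would give 1262. The interaction test was thus conservative too and may have missed changes. Camera passed the type-A list (adjusted p = 1.6e-60, and adjusted p = 6.2e-05 with an estimated correlation) and the oxidases (adjusted p = 3.6e-57, and adjusted p = 4.6e-06 with an estimated correlation). It also passed type-B regulators (adjusted p = 0.032, but adjusted p = 0.27 with an estimated correlation), synthesis genes (adjusted p = 0.044, but adjusted p = 0.12 with an estimated correlation) and, higher, fermentation enzymes (adjusted p = 0.032, but adjusted p = 0.19 with an estimated correlation). Of the later lists it passed embryo genes, higher (adjusted p = 0.004), GH3 (adjusted p = 0.0053) and light-harvesting genes (adjusted p = 0.011), which with an estimated correlation gave adjusted p = 0.51, adjusted p = 0.51 and adjusted p = 0.65. With the line as a block it further passed efflux carriers and pathogenesis-related proteins (adjusted p = 0.049 each), which without the block gave adjusted p = 0.67 and adjusted p = 0.65 with an estimated correlation. The 54 fell to 31 without the vehicle library of 54a, 32 without the BA library of 54b, 29 without the BA library of A1 and 26 without the vehicle library of B1, and to 20, 27, 20, 26 and 33 without lines 54a, 54b, A1, B1 and B4. The oxidase count was 3 without the vehicle library of B1 or without line 54a, A1 or B4. The calls of Os01g0775400 and Os03g0705800 ended in most of these omissions, with edgeR adjusted p = 0.238 for Os01g0775400 without line 54b and edgeR adjusted p = 0.19 for Os03g0705800 without line 54a.

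**Figure D3:**
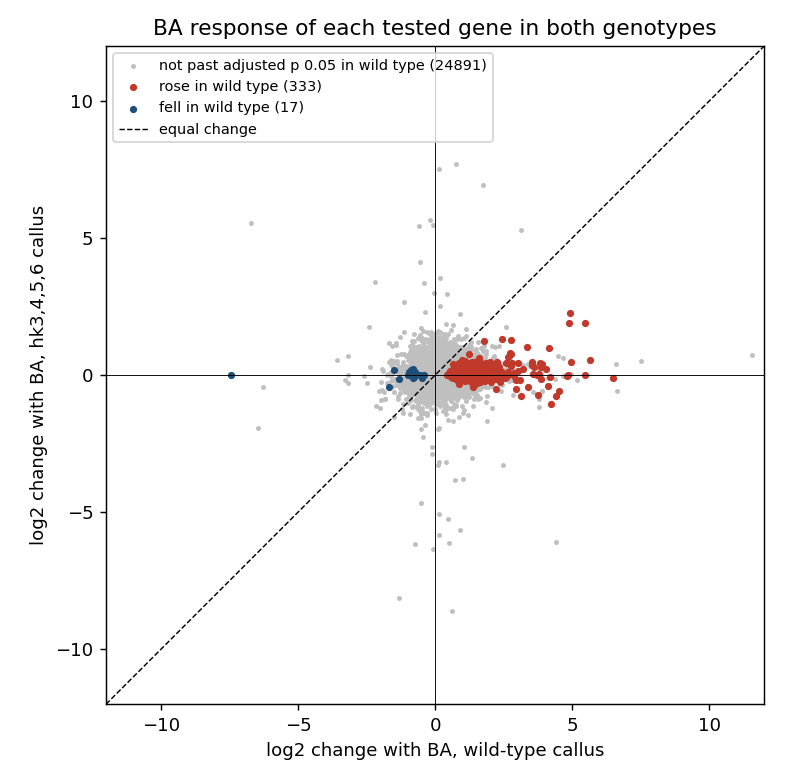
Log2 BA change of each tested gene in wild-type callus (x axis) against that in mutant callus (y axis), with the genes that passed edgeR's test in wild-type callus in red (333 higher) or blue (17 lower) and the line of equal change dashed. The 333 were chosen for their rise on the x axis, which favours a place below that line, and 54 of them passed the interaction test.

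Under vehicle, without added cytokinin, the genotypes also differed. Type-A regulators were lower in the mutant, with 6 of 10 past the test (7 adjusted over the list alone) and 0 higher. Os04g0673300 was 19.6-fold lower (1.16 ± 0.384 against 22.9 ± 7.43 CPM, edgeR adjusted p = 4.5e-05) and Os04g0524300 34.5-fold lower (0.158 ± 0.0622 against 5.69 ± 2.38 CPM). Os02g0631700 had 0 counts over the mutant group and 53 over wild type, 17.8-fold lower when the mutant group is set to a floor of 3 counts. Of 7 oxidases 3 were lower (3 adjusted over the list alone), with Os01g0775400 at 0.575 ± 0.162 against 16.6 ± 4.51 CPM (log2 −4.82 ± 0.38). Camera placed both lists lower (adjusted p = 2e-16 for type-A regulators and adjusted p = 3.9e-08 for oxidases, with adjusted p = 0.0066 and adjusted p = 0.0059 with an estimated correlation), and type-B regulators too (adjusted p = 0.017, but adjusted p = 0.29 with an estimated correlation), with no type-B member past edgeR's test.

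Among cytokinin synthesis genes 3 were higher and 1 lower in the mutant under vehicle (4 and 1 adjusted over the list alone), with Os04g0518800 higher by log2 2.57 ± 0.48 and Os03g0109300 lower at 16.4 ± 3.28 against 45.4 ± 3.73 CPM (−1.47 ± 0.15, edgeR adjusted p = 0.00031). Of 7 KNOX and WOX genes, which act in meristems, Os01g0854500 was higher (1.28 ± 0.28, and 3 higher and 1 lower adjusted over the list alone). Of 4 fermentation enzymes 1 was lower (1 higher and 2 lower adjusted over the list alone), Os05g0469600, whose edgeR call ended in 16 of 28 alternatives, among them the omission of any vehicle library, of the BA library of 54a or 54b or of any line (up to adjusted p = 0.129 without line 54b). Of 2 phosphotransfer proteins 0 passed (1 higher adjusted over the list alone). Camera passed neither synthesis, meristem nor fermentation genes (adjusted p = 0.23, adjusted p = 0.14 and adjusted p = 0.19). Aux/IAA repressors were higher for 6 of 29 and lower for 1, with Os09g0527700 higher by 1.35 ± 0.14 and Os03g0633500 by 1.51 ± 0.24 (camera adjusted p = 0.00073, but adjusted p = 0.37 with an estimated correlation). Of 7 embryo genes 3 were lower, with Os04g0546500 at 27.5 ± 10.2 against 168 ± 29.3 CPM and Os03g0699000 at 20.7 ± 5.18 against 71.6 ± 10.8 CPM (camera adjusted p = 3e-06, but adjusted p = 0.36 with an estimated correlation). The call of the embryo gene Os05g0542500 as lower ended in 7 of 28 alternatives. GH3 enzymes had 3 higher and 1 lower, and efflux carriers 2 higher. All 4 GH3 calls ended in some of 28 alternatives (Os07g0592600 in 11, Os11g0528700 in 9, Os01g0785400 in 7 and Os05g0500900 in 2). So did both efflux calls (Os02g0743400 in 13 and Os01g0643300 in 1). Cyclins had 1 higher (Os12g0588800, 1.5 ± 0.25, whose entered symbol the reference places on another chromosome, so that its place on the list is in doubt) and light-harvesting genes 1 lower (camera adjusted p = 0.74, with median log2 0.60 and mean −0.06). That light-harvesting call, of Os12g0291100, ended in 3 of 28 alternatives. Heat shock proteins passed camera as lower (adjusted p = 0.029, but adjusted p = 0.88 with an estimated correlation) with 0 of 11 members past edgeR's test.

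In all, 1463 genes passed edgeR's test between genotypes under vehicle, 950 higher and 513 lower in the mutant. Outside the lists, Os06g0658400 was higher at 110 ± 7.96 against 0.697 ± 0.957 CPM and Os10g0454200 at 47.6 ± 43.3 against 0.384 ± 0.208 CPM, the latter highest in line 13 at 96.9 CPM. Os06g0481900 was lower at 0.247 ± 0.124 against 4.29 ± 0.686 CPM and Os08g0178900 at 2.31 ± 1.59 against 36.8 ± 3.54 CPM. The 1463 fell to 747, 973 and 821 without the vehicle libraries of 13, 54a and 54b, to 625 and 575 without those of A1 and B1, and to 701, 594 and 573 without lines 54b, A1 and B1. Without the vehicle library or the line A1 the oxidase count was 1. The type-A gene Os12g0139400 lost its call in 19 of 28 alternatives, the synthesis genes Os02g0628000 and Os09g0403300 in 7 and 6, and 4 of 7 Aux/IAA genes in 2 to 9. The edgeR call of Os01g0854500 ended without the vehicle library of 13, 54a or B1 or any of these lines (up to adjusted p = 0.105), and that of Os10g0454200 without the vehicle library or line A1 or B1 (up to adjusted p = 0.0944).

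Under BA, type-A regulators and oxidases differed between genotypes in more members than under vehicle. Type-A regulators were lower in the mutant for 9 of 10 members (10 adjusted over the list alone), with Os04g0673300 380-fold lower (1.1 ± 0.42 against 421 ± 118 CPM, edgeR adjusted p = 1.5e-07). Os07g0449700 had 0 counts over the mutant group and 67 over wild type, 22.44-fold lower when the mutant group is set to a floor of 3 counts. Os02g0631700 had 1 and 1526, a ratio of 1533 (95% counting interval 275 to 60593). All 7 oxidases were lower, with Os01g0775400 at 0.592 ± 0.405 against 197 ± 43.4 CPM (log2 −8.36 ± 0.39). Of 5 type-B regulators 3 were lower, Os02g0182100 (−0.99 ± 0.14), Os02g0796500 (−0.96 ± 0.17) and Os06g0183100 (−1.04 ± 0.23), and 3 when adjusted over the list alone. Camera called the type-A and oxidase lists lower (adjusted p = 1.2e-97 and adjusted p = 5.4e-52, with adjusted p = 1.5e-05 each with an estimated correlation) and type-B regulators too (adjusted p = 8.3e-05, but adjusted p = 0.1 with an estimated correlation). Synthesis genes had 3 higher and 3 lower (7 and 6 adjusted over the list alone), fermentation enzymes 1 each way (1 each adjusted over the list alone, the lower one, Os05g0469600, losing its edgeR call in 17 of 28 alternatives, among them the omission of any line, of any BA library but that of A1, or of the vehicle library of 13, A1, B1 or B4, up to adjusted p = 0.211 without line 13) and meristem genes 0 (2 higher adjusted over the list alone), without a camera call (adjusted p = 0.76 each).

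Of the later lists under BA, Aux/IAA repressors had 7 higher and 3 lower in the mutant, nitrate genes 3 lower, GH3, light-harvesting and embryo genes 2 lower each, WRKY factors 1 higher and 2 lower, cyclins 1 higher, and JAZ, clock and heat shock genes 1 lower each. Only the heat shock list passed camera among them (adjusted p = 0.0027, but adjusted p = 0.74 with an estimated correlation). Of the 10 Aux/IAA calls 7 ended in 5 to 18 of 28 alternatives, most often for Os03g0742900 (18) and Os03g0633500 (17). All 3 WRKY calls ended in 3 to 13, the heat shock call in 9, and 1 call each of GH3 (11), light-harvesting (10), nitrate (9) and embryo genes (5). Of the 6 synthesis calls 3 ended, in 2 to 8. In all 1860 genes passed edgeR's test, 1006 higher and 854 lower. Outside the lists, Os06g0658400 (log2 8.91 ± 0.69) and Os08g0555400 (5.08 ± 0.31) were higher and Os06g0481900 (−6.41 ± 0.24) and Os03g0705800 (−6.00 ± 0.38) lower. The genotype differences under vehicle and under BA shared 885 genes of the same sign, 612 higher and 273 lower, against 37.9 and 17.36 for independent lists, and 1 gene had opposite signs. Both comparisons use the same 6 callus lines, whose own differences push both the same way, so independent lists are not the value without a genotype effect. The 1860 fell to 1015 and 1132 without the BA libraries of 13 and B4 (475 higher and 540 lower, and 487 higher and 645 lower), and to 1065, 1184, 1220 and 1104 without lines 13, 54b, A1 and B4. The lower genes outnumbered the higher ones also without line 13 (476 higher and 589 lower) or line B4 (482 and 622), in a fit of only the groups compared (587 and 612) and at an adjusted p below 0.01 (376 and 423), so which direction held more genes was not stable. The edgeR call of Os06g0183100 ended without the BA library or the line 13, 54b, A1 or B4 (up to adjusted p = 0.0733).

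The last comparison asked whether genes that BA moved in wild-type callus differed between genotypes under vehicle. Of the 333 genes that rose with BA, 38 were lower in the mutant under vehicle, against 6.77 for independent lists, and they included the type-A regulators Os04g0673300 and Os04g0524300 and the oxidase Os01g0775400. Another 22 were higher in the mutant, against 12.5. Of the 17 genes that fell with BA, 2 were higher and 2 lower in the mutant, against 0.640 and 0.346. Under BA, 255 of the 333 were lower in the mutant and 3 higher, but the 333 were chosen on the wild-type BA libraries that this difference also uses, which alone gave a correlation of −0.494 between the log2 changes of simulated unchanged groups (−0.27 observed). The 255 are thus not independent of that choice. The 2 vehicle comparisons share the wild-type vehicle libraries, whose chance values push both log2 changes the same way, and part of the excess of 22 over 12.5 may come from the shared controls. Over all genes the covariance of the log2 changes was 0.106 against 0.0514 with unchanged groups simulated against those controls in 20 draws, a difference of 0.0544, whereas their correlation was 0.309 against 0.494. Shared controls add the same covariance with or without real effects if the spread is the same, which does not hold for the correlation. The simulated groups all had the wild-type vehicle means and a spread estimated over all groups. The difference of 0.0544 may therefore come in part from these settings and does not by itself show a real overlap. The 38 fell to 25 without the vehicle library of 54b, to 16, 17 and 23 without those of A1, B1 and B4, and to 20, 12, 14 and 23 without lines 54b, A1, B1 and B4.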

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

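The test of library size and the test of cell type markers were chosen only after the genotype difference had been seen. The results given here are those for which the BA responses of wild-type and mutant callus differed in the interaction test.

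The interaction test called 54 genes. The log2 BA response, mutant minus wild type, was −1.75 for Os04g0442300, −3.32 for Os01g0952500, −4.27 for Os04g0673300, −4.47 for Os11g0143300 and −5.12 for Os12g0139400, all type-A response regulators. Os11g0143300 and Os12g0139400 are the near-identical pair and not separate measurements. The same difference was −3.15 for Os01g0197700, −2.41 for Os10g0483500, −1.88 for Os01g0940000, −3.54 for Os01g0775400 and −2.05 for Os08g0460600, all cytokinin oxidases. It was −3.84 for Os03g0705800 and −3.75 for Os01g0153800, which are on no list. Under some alternatives the edgeR interaction call ended, for Os01g0775400 and Os03g0705800 in 17 and 11 of them, for Os01g0940000 (without the vehicle library of B1, adjusted p = 0.0542, and without line 54a, A1 or B4, up to adjusted p = 0.097) and for Os04g0442300 (without line 54a, adjusted p = 0.0524).

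The first pattern is how far the 333 genes that rose with BA in wild-type callus moved in mutant callus. Their mean log2 change, relative to the median of all tested genes, was 0.106 over the 3 mutant lines (0.191 in line 13, −0.00766 in 54a and 0.136 in 54b), which is 6.79% of the mean of 1.57 ± 0.160 (SD) in the 3 wild-type lines, where the genes were selected. The share of these genes higher with BA was 74.5%, 49.5% and 66.7% in lines 13, 54a and 54b. A small residual response without the 4 receptors may remain or may be absent, because 1 line lies at about 0, the highest line reaches 12.2% of the wild-type mean, and the tests differ. The directional fry test did not pass (0.175, or 0.267 with the line as a block), while camera, which compares the set with other genes, gave 7.3e-08 at the preset correlation and 0.0763 with the estimated one, and 240 of the 333 genes were fitted higher.

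The second pattern is the genotype difference under vehicle. Unequal library size is argued against, since mean totals differed by a ratio of 1.00. Called genes of the same sign lay next to each other by locus number in 135 pairs, against a median of 46 and a 95th percentile of 57 in 10000 random draws (permutation p = 1e-04, the smallest they can give), so local sequence or copy-number differences between the lines may contribute. The 350 genes of the wild-type BA response, where no sequence differs, also lay in 24 neighbouring pairs against a median of 4. Such clustering thus does not separate that explanation from shared regulation of neighbours. Reads divided between near-identical copies were not set apart either. A pair of genes called higher under vehicle had the same estimate, log2 4.70 ± 0.98. Another share of other cell types also stays open, with list medians of log2 −1.49 for embryo (7 of 8 genes tested in this callus, with Os05g0542500, the most abundant in wild type, at 97.5 CPM in mutant and 273 CPM in wild type), 0.55 for meristem (7 of 9) and 0.60 for green-cell genes (8 of 17, with a mean of −0.06, 0 higher and 1 lower, and no camera call), and loss of the receptors in itself was not tested apart from line history, since each line has 1 genotype.

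The third pattern is genes at 0 counts in all 6 libraries of a genotype and at 10 or more in each library of the other, chosen after their values were seen. Os11g0625900 had 0 counts in the mutant and 135 to 233 in wild-type libraries, 209-fold lower under vehicle when the mutant group is set to a floor of 3 counts. Os08g0555600 (210 to 421 counts in mutant libraries) and Os01g0207300 (63 to 110) had 0 counts in wild type. These 3 genes formed 0 neighbouring pairs against a random median of 0, so loss or divergence of a chromosomal stretch could neither be supported nor excluded with so few genes. Genes outside this rule were not counted. Os08g0555400, close to Os08g0555600 by locus number, was such a gene and was higher in the mutant (log2 5.08 ± 0.31 under BA).

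Splits of the 6 libraries or lines into 3 and 3 number 10, the real one included, so the share of splits with as many genes can never be under 0.05. A real effect also widens the spread within the mixed groups of the other splits, which lowers their counts. The count of splits with as many genes, the real one included, was 1 for the BA response of wild-type callus (350 genes, highest other 0, also for the 3 other splits that part every line), 10 for mutant callus (0 genes, highest other 3), 1 for the interaction with the line as a block (60 genes, highest other 12), 1 for the genotype difference under vehicle (1463 genes, highest other 0) and 1 for that under BA (1860 genes, highest other 269, from lines 13 and 54b with B1).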

How the results depend on the processing

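All alternatives were fixed before the data were examined. No named gene changed direction while called. Under each scaling of the counts, the median log2 change of all genes was at most 0.0222 in absolute value. Of called list members and top genes together, 16 of 39 kept the call under each alternative in the BA response of wild-type callus (12 of 13 type-A regulators and oxidases), 8 of 16 in the interaction (7 of 10), 26 of 53 in the genotype difference under vehicle (5 of 9) and 46 of 71 under BA (15 of 16). The BA response of mutant callus stayed at 0 genes in each alternative but DESeq2. The receptor count was 2 or 3 throughout. Where a group lies at or near 0 counts, depth limits how precisely a fold can be given.

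The DESeq2 Wald test gave 624 genes for the BA response of wild-type callus, 2 for mutant callus, 171 for the interaction, 2391 for the genotype difference under vehicle and 72 for the overlap. A fit of only the groups compared gave 2317 under vehicle and 1199 under BA. The interaction cannot be fitted that way, nor a genotype difference with the line as a fixed block. An adjusted p below 0.01, stricter by construction, left 175, 25, 447 and 799 genes for the wild-type response, the interaction and the genotype difference under vehicle and BA, and a 2-fold minimum left 1187 for the last. The overlap with the genotype difference under BA was 255. Among the lists fixed beforehand, 2 of 5 camera calls remained with the estimated correlation for the interaction and 2 of 4 for the genotype difference under BA. Fry passed receptors and type-B regulators as lower under BA (fry adjusted p = 0.0019 and 0.0028) and under vehicle (0.0015 and 0.035). It passed synthesis genes as higher under vehicle (0.035) and in the wild-type response (0.019). Under vehicle it also passed Aux/IAA genes, higher, and embryo genes, lower (0.027 each). Beyond type-A regulators and oxidases, fry passed no list in the interaction, and no list in mutant callus. With a library or a line left out, counts ranged from 93 to 384 for the wild-type response, 20 to 55 for the interaction, 573 to 1814 under vehicle, 1015 to 1950 under BA and 12 to 41 for the overlap. Fewer samples lower the power, but some omissions raised a count, and the cause was not tested for these or the other moves. The replicate block (callus line) gave 401 genes for the wild-type response (307 shared), 0 for mutant callus and 60 for the interaction (39 shared), and beyond the calls given in the report it ended those of Os06g0729000, Os03g0675300 and Os02g0687600 and changed no other call of a named gene or list.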

Other observations

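The wild-type lines differed more between BA and vehicle than the mutant lines did. Across 20051 genes the SD of the log2 difference between the libraries of a line was 0.536, 0.494 and 0.410 in wild-type lines A1, B1 and B4 and 0.294, 0.263 and 0.339 in mutant lines 13, 54a and 54b. Without the called genes it was 0.499, 0.464 and 0.377 in wild type and 0.294, 0.262 and 0.338 in the mutant.

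The first principal component, 45.8% of the variance, separated the genotypes, and line 13 lay farthest from wild type at −83.3 (BA) and −64.4 (vehicle). On the second, 12.2%, the BA libraries of A1 and B1 stood at 44.7 and 49.5 and that of B4 at 5.41. Their vehicle libraries stood at −35.4, −27.2 and −2.82. Mutant libraries also differed on it, at 21.4 (BA) and 1.80 (vehicle) in line 13 and −6.26 and −28.6 in 54b. In 54a the BA library lay lower, at −17.5 against −4.98. Os10g0454200 was at 149 and 96.9 CPM in line 13 (BA and vehicle), 23.5 and 15.9 CPM in 54a, and 5.44 and 30.0 CPM in 54b.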
